A study of Mus musculus with 32 samples.

How the data were processed

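Expression was measured on 32 Affymetrix arrays of CD4+ T cells from DO11.10 mice, whose T cells carry a receptor for an ovalbumin (OVA) peptide, cultured with peritoneal macrophages as antigen-presenting cells. Cells sorted after 48 h were measured on 23 MoGene-2_0-st arrays and cells sorted after 72 h on 9 HT_MG-430_PM arrays, each from 100 ng of RNA. The deposited values are log2 expression per probe set made by the authors with RMA in Affymetrix Expression Console 1.1, per the labels. Which arrays were normalized together and which probe filters were applied is not stated. Array medians over all probe sets lay between 5.45 and 5.75 at 48 h and between 3.87 and 4.04 at 72 h. No pair of arrays was identical, and correlations between arrays ran from 0.884 to 0.9898 at 48 h and from 0.866 to 0.9949 at 72 h. The number of arrays limits the precision. Nothing in the labels says whether replicates are separate cultures or animals, so the p-values measure the spread between these samples.

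Probe sets were assigned to genes with the platform annotation. Of 41345 probe sets at 48 h, 23521 named 1 gene, 1814 several and 16010 none, which left 22180 genes. Of 45037 at 72 h, 28898 named 1 gene, 551 several and 15588 none, which left 17097 genes. A gene with several probe sets was represented by the one with the highest mean over the arrays. The platforms were never put in a common fit.

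Differences between groups were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with all groups of a platform in the same fit. Moderated p-values were adjusted by Benjamini-Hochberg within each of 16 comparisons, and a gene was called at an adjusted p below 0.05. All tests were two-sided. Whether the effect of antigen differed between low arginine, leucine and lysine media was tested with limma's moderated F test. A set of 25 gene lists was tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg over the lists of a comparison, and again with an estimated correlation and with fry. Fold changes of pairs of comparisons were correlated across genes. Where a pair shared its control arrays, the correlation that sharing alone gives was simulated 100 times. Tables and plots were made in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

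The comparisons, the tests, the gene lists and the rule for naming genes were fixed before the data were examined. The rule took, for each comparison, the 6 called genes with the largest rise and the 6 with the largest fall whose groups of arrays did not overlap, leaving out genes without a symbol of their own. It added up to 4 called members of each list, and fixed genes such as Arg1, Il2, Asns and Cdk1. Genes named for the interaction, and Atp2a2 and Pgap1, were chosen after their values were seen, as was a list of 18 mesothelial and stromal markers. The lists cover the amino acid response (ATF4 targets), aminoacyl-tRNA synthetases, amino acid transporters, G1/S and DNA replication, G2/M and mitosis, naive and quiescent T cells, T cell activation, helper cytokines and chemokines, regulatory T cells, inhibitory receptors and anergy, glycolysis, cholesterol synthesis, ribosome biogenesis, oxidative phosphorylation, the unfolded protein response, p53 targets, autophagy, the interferon response and CD4 T cell identity. Lists of markers of macrophages, alternatively activated macrophages, B cells, granulocytes and mast cells, CD8 T and NK cells, and dendritic cells stand for other cells that a culture or a sort gate could hold.

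Titles number the replicates. Over the 5000 genes with the highest mean, the deviations of arrays with the same number from their group means were correlated. Every pair was above 0.1 for the IL-4/IL-10 effect at 72 h (0.16 to 0.26) and for low arginine against low leucine with antigen (0.29 to 0.39). There the numbers were treated as pairing only in alternative fits with a block, whose counts are given. The gene and list values of both comparisons come from the fit without a block. Submitter IDs form consecutive runs, and the full-medium arrays at 48 h belong to other runs than the low amino acid arrays. For the IL-4/IL-10 effect at 72 h, the replicate 3 arrays come from different runs.

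The steps were tested on simulated data made from these arrays. With 200 genes changed in each of 5 simulations, 36.6%, 83.0% and 99.7% of changes of 1.5, 2 and 4-fold were called at 48 h, and 29.0%, 69.7% and 95.4% at 72 h. False calls averaged 5.4 and 7.2 genes. Lists shifted by 0.5 were called in 25 of 25 cases on both platforms, and unshifted lists in 1 of 100 cases at 48 h and 0 of 100 at 72 h. The simulated noise was independent between genes and had the same spread in all groups. The list cases therefore cannot show how often camera at the preset correlation calls unshifted lists whose genes vary together. Nor do the recovered shares and false calls cover genes whose spread differs between groups. The mean G2/M level, for example, had an SD of 0.77 with IL-4/IL-10 and 0.07 without at 48 h, and 0.94 and 0.25 at 72 h.

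Alternatives fixed beforehand were a fit of the compared groups alone, leaving out genes below the 40th percentile of the mean, quantile normalization of the deposited values, centring each array on its median over the compared genes, the median of a gene's probe sets, no intensity trend, array weights, a block by replicate number or by ID run, leaving out each array in turn, and a minimum change of 2-fold. Chosen after seeing the data were a replicate block over all groups, leaving out ID run 1, a block by Xist level, the added settings for the list tests (the ID-run block, leaving out each array and the 40th percentile), and leaving out genes that followed the mesothelial markers at 72 h (rank correlation above 0.8). The last was run but supports no statement and enters no total in the text, since these markers differ between the groups and following them selects genes lower with antigen. Probe sets without a single gene were left out of the comparisons and counted apart.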

Results

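The arrays measured how helper T cells respond to antigen in medium with little of an amino acid, or on macrophages that had been treated beforehand with IL-4 and IL-10. T cells were cultured on thioglycollate-elicited macrophages with or without the OVA peptide that their receptor recognizes, then sorted as viable CD4+ singlets. At 48 h, 3 arrays each held cells given antigen in full medium, in full medium on macrophages that both cytokines had treated and that were then washed, or in medium with arginine, leucine or lysine at 1% of normal. Cells without antigen in the low media had 2 arrays for low arginine and 3 each for low leucine and low lysine. At 72 h, 3 arrays each held cells without antigen, with antigen, and with antigen on pretreated macrophages. Changes below are log2 fold changes ± SE from limma with n = 3 arrays per group unless stated.

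Antigen for 72 h raised genes of T cell activation and division in full medium. Gzmb, which encodes granzyme B, rose by 8.81 ± 0.28 (adjusted p = 2.45e-08), the transcription factor Irf4 by 6.20 ± 0.34 (adjusted p = 3.06e-07), and the inhibitory receptor Ctla4 by 5.93 ± 0.40 (adjusted p = 9.69e-07). Il2ra, the IL-2 receptor alpha chain, rose by 5.53 ± 0.34 (adjusted p = 5.91e-07), and Tg, Nkg7 and Tnfrsf4 were the other large rises (6.52 ± 0.31, 6.03 ± 0.49 and 5.67 ± 0.19). Of 24 T cell activation genes, 19 rose and 2 fell, and the counts were the same adjusted over the list alone (median 3.48, camera adjusted p = 1.23e-10, adjusted p = 0.00731 with an estimated correlation). All 31 G2/M genes rose (31 adjusted over the list alone, median 3.15), among them the mitotic kinases Aurkb (4.65 ± 0.42) and Bub1 (4.24 ± 0.47), as did 33 of 35 G1/S genes (33 adjusted over the list alone, median 2.47). Both lists passed camera (adjusted p = 4.02e-15 and 5.34e-16, and adjusted p = 0.26 for each with an estimated correlation). Biosynthetic lists rose too: 16 of 17 aminoacyl-tRNA synthetases, 23 of 25 ribosome biogenesis genes, 17 of 19 cholesterol genes, 11 of 14 glycolysis genes and 11 of 16 oxidative phosphorylation genes (16, 23, 19, 12 and 13 adjusted over the list alone). Their camera adjusted p was at most 3.39e-05, and 0.258 to 0.26 with an estimated correlation. Asns, which makes asparagine, rose by 2.52 ± 0.12 (adjusted p = 1.73e-07) and Psat1, of serine synthesis, by 2.93 ± 0.17 (adjusted p = 3.54e-07). Of the 29 ATF4 targets 17 rose and 7 fell (17 and 7 adjusted over the list alone, camera adjusted p = 0.0205, adjusted p = 0.285 with an estimated correlation).

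The largest falls with antigen at 72 h were in genes that T cells do not usually express. Upk3b, a mesothelial membrane protein, fell by 7.40 ± 0.24 (adjusted p = 2.45e-08), Cdh11, a mesenchymal cadherin, by 7.74 ± 0.67 (adjusted p = 5.12e-06), and Trf, Lpl, Osr1 and Ogn by 7.76 ± 0.71, 7.59 ± 0.55, 7.53 ± 0.45 and 7.40 ± 0.58. Of 24 macrophage genes, 16 fell (18 adjusted over the list alone, median -1.86, camera adjusted p = 1.49e-06, adjusted p = 0.289 with an estimated correlation). Among its members were Cd14 (-6.04 ± 0.46), Apoe (-5.84 ± 0.33) and Lyz2 (-5.59 ± 0.83). The mean level of this list without antigen was 5.10 in replicate 1, against 7.17 and 6.66 in replicates 2 and 3, whereas mesothelial and stromal markers stood at 8.77, 8.85 and 8.69. Arg1, the arginase of alternatively activated macrophages, fell by 4.65 ± 0.71 (adjusted p = 0.00031). The mean level of the added list of 18 mesothelial and stromal markers was 8.77 ± 0.08 (SD, n = 3) without antigen and 3.94 ± 0.18 (SD, n = 3) with it. Of 19 naive and quiescent T cell genes, 8 fell and 2 rose (10 and 2 adjusted over the list alone, camera adjusted p = 0.0205, adjusted p = 0.467 with an estimated correlation), with a median of -0.49 that turned to 0.02 with centred arrays. Klf2, a transcription factor of resting T cells, fell by 2.82 ± 0.39 (adjusted p = 0.000163). CD4 T cell identity genes rose in 11 of 16 cases (11 adjusted over the list alone, median 0.81, camera adjusted p = 9.58e-05, adjusted p = 0.26 with an estimated correlation), while Cd3e measured 0.29 ± 0.29 (adjusted p = 0.493). At 48 h this list had antigen medians of 0.30, 0.15 and 0.11 in low arginine, leucine and lysine. With quantile normalization these turned to -0.09, -0.26 and -0.24. Whether RNA of other cells in the arrays without antigen enlarged this and other rises at 72 h was not tested. In total 6527 of 17097 genes were called, 3545 higher (54.3%) and 2982 lower. The median over the compared genes was lower in the arrays with antigen (-0.51), while the median log2 fold change of these genes was 0.020. Centring each array on its median raised every log2 fold change by the same amount. It gave 12819 called genes, 86.0% of them higher, and quantile normalization gave 4054 higher and 2915 lower.

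Pretreating the macrophages with IL-4 and IL-10 raised ATF4 targets and lowered cholesterol synthesis in antigen-stimulated cells at 72 h. Of 29 ATF4 targets, which respond to missing amino acids, 21 rose and 0 fell (24 and 0 adjusted over the list alone, median 1.28, camera adjusted p = 2.66e-20, adjusted p = 0.0206 with an estimated correlation). Nupr1, a stress-induced chromatin protein, rose by 3.76 ± 0.29 (adjusted p = 7.96e-05), Cth, of cysteine synthesis, by 2.97 ± 0.27 (adjusted p = 0.000175), the pseudokinase Trib3 by 2.52 ± 0.21 (adjusted p = 9.43e-05), and Chac1, which degrades glutathione, by 2.11 ± 0.23 (adjusted p = 0.000453). All 19 cholesterol synthesis genes fell (19 adjusted over the list alone, median -2.10, camera adjusted p = 5.97e-30, adjusted p = 0.0416 with an estimated correlation). Fdps and Cyp51 of that list fell by 3.57 ± 0.18 and 2.96 ± 0.22, and the fatty acid desaturases Fads2 and Scd1, outside it, by 3.69 ± 0.25 and 3.49 ± 0.38. Il2, the T cell growth factor, rose by 4.74 ± 0.64 (adjusted p = 0.00181), Tnfrsf19 by 4.78 ± 0.20 (adjusted p = 2.13e-06) and Csf2 by 3.34 ± 0.34 (adjusted p = 0.000341). Slc7a3, a transporter of arginine and lysine, rose by 2.42 ± 0.24, with 6 of 14 transporters higher (7 adjusted over the list alone, camera adjusted p = 5.87e-06, adjusted p = 0.162 with an estimated correlation). Of 31 G2/M genes, 23 fell (31 adjusted over the list alone, median -1.59, camera adjusted p = 1.45e-19, adjusted p = 0.306 with an estimated correlation). Of 19 naive and quiescent genes 6 rose (11 adjusted over the list alone, camera adjusted p = 2.39e-05, adjusted p = 0.306 with an estimated correlation). Klf2 was among them (2.42 ± 0.39).

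Arg1 measured 2.15 ± 0.71 (adjusted p = 0.0851) in the same comparison, and 4 of 17 genes of alternatively activated macrophages rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.013, adjusted p = 0.162 with an estimated correlation). Mesothelial and stromal markers averaged 4.82 ± 0.68 (SD, n = 3) with pretreatment, highest in replicate 1 (5.57), where the G2/M genes averaged 7.10, the lowest of the 3 arrays. Cxcl1 (4.21 ± 0.70) and Saa3 (3.91 ± 0.61), which myeloid and stromal cells express, and Gcat (-3.51 ± 0.27) and St14 (-3.10 ± 0.29) were among the largest changes, as were Serpinb2 (5.38 ± 1.19), Iltifb (4.32 ± 0.98) and Cox6b2 (-3.23 ± 0.71). The calls of Serpinb2 and Cox6b2 ended without antigen replicate 1 or 3 or pretreated replicate 1 or 3, and that of Iltifb without antigen replicate 2 or 3 or pretreated replicate 1 or 3 (highest adjusted p = 0.0889, 0.0867 and 0.0885). In all 1656 genes were called, 646 higher and 1010 lower. With the replicate number as a block there were 1846 in the same fit, and 1530 in a fit of the compared groups alone, which had 1009 without a block. The count fell to 1035 without antigen replicate 1, 538 without antigen replicate 3, 919 without pretreated replicate 1 and 495 without pretreated replicate 3.

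Cells given antigen on pretreated macrophages for 72 h were also compared with cells without antigen, on the same arrays. Each log2 fold change is by construction the sum of the antigen and pretreatment changes above, so it lends neither of them separate support. Gzmb rose by 7.30 ± 0.28 (adjusted p = 4.17e-08), Irf4 by 7.19 ± 0.34 (adjusted p = 1.41e-07), Il2 by 7.18 ± 0.64 (adjusted p = 7.29e-06) and Lta, which encodes lymphotoxin alpha, by 6.60 ± 0.31 (adjusted p = 1.41e-07). Slc7a3 rose by 5.28 ± 0.24, Cth by 4.72 ± 0.27 and Asns by 3.02 ± 0.12, and 23 of 29 ATF4 targets rose and 2 fell (23 and 2 adjusted over the list alone, median 2.24, camera adjusted p = 3.12e-11, adjusted p = 0.0504 with an estimated correlation). T cell activation genes rose in 19 of 24 cases and fell in 1 (19 and 1 adjusted over the list alone, median 3.07, camera adjusted p = 1.27e-13, adjusted p = 0.00343 with an estimated correlation). Cholesterol genes fell in 16 of 19 cases (16 adjusted over the list alone, median -0.997, camera adjusted p = 1.83e-07, adjusted p = 0.238 with an estimated correlation). Of 31 G2/M genes 19 rose (22 adjusted over the list alone, median 1.40, camera adjusted p = 2.42e-07, adjusted p = 0.482 with an estimated correlation). Clca3a2 (-7.13 ± 0.22), Upk3b (-6.83 ± 0.24), Cemip (-6.77 ± 0.25) and Acta2, a smooth muscle actin (-6.65 ± 0.30), were among the largest falls, and 13 of 24 macrophage genes fell (18 adjusted over the list alone, camera adjusted p = 3.62e-06, adjusted p = 0.376 with an estimated correlation). For p53 targets the median (0.11) and the mean (-0.03) differed in sign, as for naive and quiescent genes (0.06 and -0.10), and neither list passed camera (adjusted p = 0.924 for both). In all 5557 genes were called, 2892 higher (52.0%) and 2665 lower. Centring gave 12195, 85.6% of them higher (difference of medians over the compared genes -0.44, median log2 fold change of these genes 0.040). Quantile normalization gave 3324 higher and 2602 lower.

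**Figure D1:**
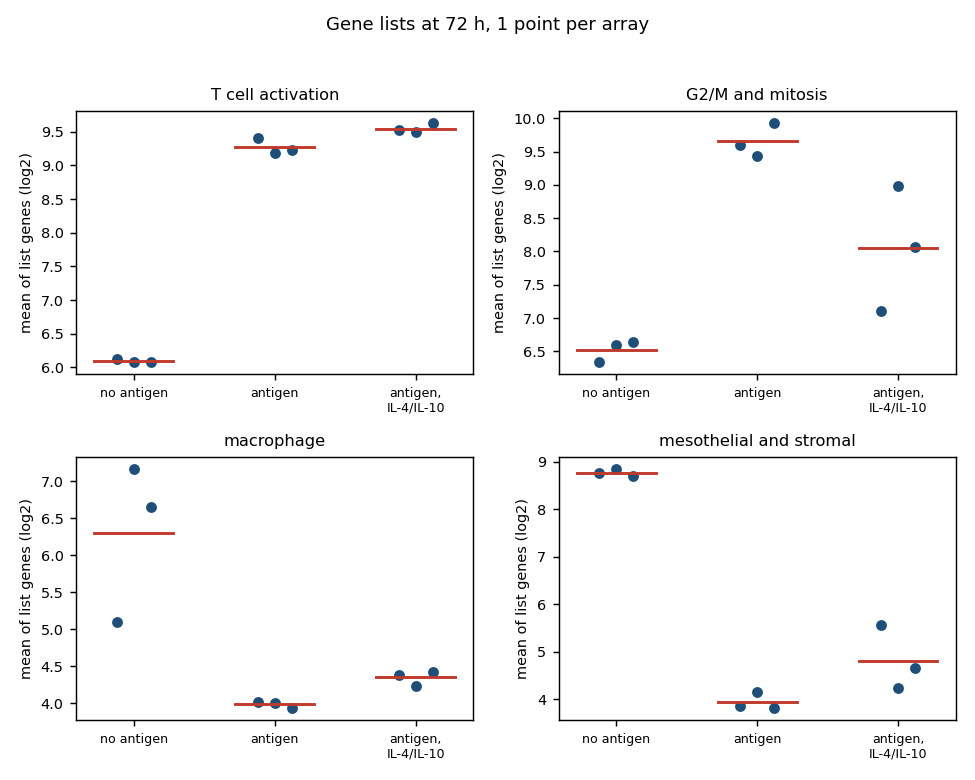
Mean level of the genes of a list (log2, vertical axis) in each group at 72 h (horizontal axis), with 1 point per array and a red line at the group mean. Mesothelial and stromal markers averaged 8.77 without antigen and 3.94 with it.

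IL-4/IL-10 pretreatment also raised ATF4 targets and lowered cholesterol and cell division genes at 48 h. Of 30 ATF4 targets 17 rose and 0 fell (21 and 0 adjusted over the list alone, median 0.69, camera adjusted p = 3.98e-22, adjusted p = 0.00074 with an estimated correlation). The list included Cth at 2.44 ± 0.28 (adjusted p = 7.86e-06), Nupr1 at 2.15 ± 0.18 (adjusted p = 4.36e-08), Chac1 at 1.61 ± 0.15 and Ddit3, a stress transcription factor, at 1.54 ± 0.17. Asns measured 0.69 ± 0.22 (adjusted p = 0.0594). All 19 cholesterol genes fell (19 adjusted over the list alone, median -1.74, camera adjusted p = 1.79e-45, adjusted p = 0.000379 with an estimated correlation). Fdps and Hmgcs1 fell by 3.01 ± 0.22 and 2.71 ± 0.16, and Fads2 and Scd1 by 4.90 ± 0.21 and 4.21 ± 0.29. All 31 G2/M genes fell (31 adjusted over the list alone, median -1.87, camera adjusted p = 2.39e-36, adjusted p = 0.0458 with an estimated correlation). These included Plk1, a mitotic kinase (-2.42 ± 0.30), and Cdk1 (-2.40 ± 0.44, adjusted p = 0.00116). Of 35 G1/S genes 28 fell and 2 rose (33 and 2 adjusted over the list alone, median -0.83, camera adjusted p = 6.81e-24, adjusted p = 0.0458 with an estimated correlation), and the histone gene H2bc12 fell by 3.31 ± 0.68. Il2 rose by 2.22 ± 0.29 (adjusted p = 2.96e-05), Ermn by 2.30 ± 0.26 and Cd69, an early activation marker, by 1.11 ± 0.13, while Il2ra measured 0.01 ± 0.13 (adjusted p = 0.983). Helper cytokines and chemokines rose in 6 of 21 cases and fell in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 9.12e-05, adjusted p = 0.0424 with an estimated correlation). Transporters rose in 5 of 15 (5 adjusted over the list alone, camera adjusted p = 6.11e-06, adjusted p = 0.0458 with an estimated correlation).

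Markers of alternatively activated macrophages were higher in the same arrays. Chil3 rose by 4.94 ± 0.25 (adjusted p = 1.31e-11), Retnla by 3.54 ± 0.26 (adjusted p = 8.69e-09), Arg1 by 1.84 ± 0.24 (adjusted p = 3.45e-05) and the mannose receptor Mrc1 by 1.23 ± 0.22 (adjusted p = 0.000863). Of 17 genes of that list 5 rose (8 adjusted over the list alone, camera adjusted p = 2.75e-08, adjusted p = 0.00074 with an estimated correlation). Of 24 general macrophage genes 9 rose (12 adjusted over the list alone, median 0.38, camera adjusted p = 2.78e-08, adjusted p = 0.101 with an estimated correlation). Mean G2/M levels in the pretreated arrays were 6.39, 6.54 and 7.80, and the array at 7.80 had the lowest macrophage level (6.90, against 7.12 and 7.38). Of 16 oxidative phosphorylation genes 10 fell (11 adjusted over the list alone, camera adjusted p = 4.38e-09, adjusted p = 0.089 with an estimated correlation). Of 16 unfolded protein response genes 8 fell and 3 rose (9 and 3 adjusted over the list alone, camera adjusted p = 0.00854, adjusted p = 0.337 with an estimated correlation). In all 1916 of 22180 genes were called, 600 higher and 1316 lower, while quantile normalization gave 855 and 883. The count was 1148 without antigen replicate 2 and 1162 without pretreated replicate 1, and leaving out antigen replicate 3 gave 1232.

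The pretreatment effects at both times were alike across genes. Over 15938 genes matched by symbol, which share no arrays, Pearson's r was 0.57 and Spearman's rho 0.46, and r ran from 0.50 to 0.60 when 1 array was left out. Both comparisons called 193 genes higher (18.7 by chance) and 437 lower (71.8 by chance), with 2 called in opposite directions. This and 3 correlations with the low media are across genes, which are not independent replicates. ATF4 targets (0.69 and 1.28) and cholesterol genes (-1.74 and -2.10) had medians of the same sign at both times.

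Low arginine medium, against full medium with antigen at 48 h, raised ATF4 targets and lowered cholesterol and glycolysis genes. Of 30 ATF4 targets 19 rose and 0 fell (28 and 0 adjusted over the list alone, median 0.90, camera adjusted p = 2.1e-39, adjusted p = 8.05e-05 with an estimated correlation). Among its members were Nupr1 at 3.06 ± 0.18 (adjusted p = 1.65e-10), Cth at 2.39 ± 0.28 (adjusted p = 1.26e-05), Sesn2, an inhibitor of mTORC1 signalling, at 1.79 ± 0.25 and Trib3 at 1.72 ± 0.22. Slc7a3 rose by 2.22 ± 0.16 (adjusted p = 8e-09), and Tnfrsf19 and Cox6a2 by 1.95 ± 0.17 and 1.88 ± 0.22. Cholesterol genes fell in 18 of 19 cases (19 adjusted over the list alone, median -1.68, camera adjusted p = 1.09e-51, adjusted p = 9.11e-05 with an estimated correlation), and Fads2 and Scd1 fell by 4.62 ± 0.21 and 4.60 ± 0.29. Of 14 glycolysis genes 11 fell (14 adjusted over the list alone, median -0.85, camera adjusted p = 1.06e-18, adjusted p = 0.0267 with an estimated correlation). The glucose transporter Slc2a3 fell by 1.79 ± 0.32 and Hk2, a hexokinase, by 1.29 ± 0.20. Egln3, an oxygen-sensing hydroxylase, fell by 4.10 ± 0.33 (adjusted p = 4.07e-08), the potassium channel gene Kcnma1 by 4.90 ± 0.41 (adjusted p = 5.55e-08) and Gzmb by 2.17 ± 0.46 (adjusted p = 0.00599). Of 17 p53 targets 4 rose (8 rose and 1 fell adjusted over the list alone, camera adjusted p = 6.06e-06, adjusted p = 0.0451 with an estimated correlation). Trp53inp1 rose by 1.48 ± 0.13. Of 9 CD8 T and NK genes 2 fell (2 adjusted over the list alone, camera adjusted p = 0.00771, adjusted p = 0.0451 with an estimated correlation). Eomes, a T-box factor of effector cells, fell by 1.42 ± 0.19. G2/M genes fell in 1 of 31 cases (1 adjusted over the list alone, median -0.32, camera adjusted p = 0.0163, adjusted p = 0.778 with an estimated correlation), and Cdk1 measured -0.49 ± 0.44 (adjusted p = 0.671). Every low arginine array had a lower mean G2/M level (8.47 to 8.67) than every full-medium array (8.77 to 8.89). The fit shares its estimate of the spread over all groups. The SD of this level was 0.99 in low lysine, 0.11 in low arginine and 0.07 in full medium. The few calls therefore cannot show that G2/M genes were spared. With the compared groups alone, 2472 genes were called. Arg1 fell by 1.76 ± 0.24, in a list of alternatively activated macrophage genes with a median of 0.09 and a mean of -0.33 (camera adjusted p = 0.0849). In all 1036 genes were called, 334 higher and 702 lower, while quantile normalization gave 450 and 473. Leaving out 1 array gave 672, 589 and 606 for antigen replicates 1, 2 and 3 and 593 and 577 for low arginine replicates 1 and 2.

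Low leucine medium raised Il21, ATF4 targets and p53 targets. Il21, a helper cytokine, rose by 2.36 ± 0.37 (adjusted p = 0.000431), and Rgs16, a regulator of G protein signalling, by 2.05 ± 0.17 (adjusted p = 7.77e-08). Of 30 ATF4 targets 15 rose and 0 fell (22 and 0 adjusted over the list alone, median 0.60, camera adjusted p = 2.95e-30, adjusted p = 0.000189 with an estimated correlation). Nupr1 and Ddit3 rose by 2.07 ± 0.18 and 1.96 ± 0.17, and outside the list Slc7a3, Ajuba and Adh1 rose by 2.10 ± 0.16, 2.18 ± 0.25 and 2.07 ± 0.17. Of 17 p53 targets 7 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.62, camera adjusted p = 1.92e-12, adjusted p = 0.00334 with an estimated correlation). These included Zmat3 at 1.17 ± 0.21 and the death receptor Fas at 0.92 ± 0.15. Inhibitory receptor genes rose in 5 of 16 cases (5 adjusted over the list alone, camera adjusted p = 0.000537, adjusted p = 0.0456 with an estimated correlation). Among its members were Tigit at 1.98 ± 0.33 and Lag3 at 1.24 ± 0.20. Helper cytokine genes rose in 4 of 21 cases and fell in 1 (7 and 3 adjusted over the list alone, camera adjusted p = 9.24e-05, adjusted p = 0.0271 with an estimated correlation). Cholesterol genes fell in 18 of 19 cases (19 adjusted over the list alone, median -1.37, camera adjusted p = 1.83e-53, adjusted p = 0.00015 with an estimated correlation), and Kcnma1, Fads2 and Scd1 fell by 5.07 ± 0.41, 4.90 ± 0.21 and 4.63 ± 0.29. Interferon response genes fell in 5 of 20 cases (7 adjusted over the list alone, median -0.30, camera adjusted p = 2.84e-06, adjusted p = 0.0255 with an estimated correlation). Stat2 and Rtp4 fell by 0.88 ± 0.17 and 1.15 ± 0.20, and Ifit1bl1, outside the list, by 2.76 ± 0.28. Alternatively activated macrophage genes fell in 5 of 17 cases (6 adjusted over the list alone, camera adjusted p = 0.00133, adjusted p = 0.0271 with an estimated correlation). These included Arg1 at -1.59 ± 0.24 and Ccl22 at -2.28 ± 0.31. G2/M genes fell in 1 of 31 cases (5 adjusted over the list alone, median -0.52, camera adjusted p = 2.12e-07, adjusted p = 0.388 with an estimated correlation). Every low leucine array had a lower mean G2/M level (8.09 to 8.44, SD 0.18) than every full-medium array (8.77 to 8.89, SD 0.07). The spread shared with low lysine (SD 0.99) again means that few calls cannot show these genes to be spared. With the compared groups alone, 1654 genes were called. In all 603 genes were called, 256 higher and 347 lower, while quantile normalization gave 302 and 272. Leaving out 1 array gave 389, 358 and 339 for antigen replicates 1, 2 and 3 and 401, 359 and 399 for low leucine replicates 1, 2 and 3.

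Low lysine medium lowered the G2/M genes and raised Il2. All 31 G2/M genes fell (31 adjusted over the list alone, median -1.88, camera adjusted p = 7.61e-32, adjusted p = 0.0943 with an estimated correlation). The list included Cdk1 at -2.14 ± 0.44 (adjusted p = 0.00393), Hmmr at -2.46 ± 0.44 and Ccnb2, a mitotic cyclin, at -2.29 ± 0.42. Of 35 G1/S genes 26 fell and 1 rose (30 and 1 adjusted over the list alone, median -0.84, camera adjusted p = 3.68e-18, adjusted p = 0.104 with an estimated correlation), and H2bc12 fell by 3.42 ± 0.68. Il2 rose by 1.75 ± 0.29 (adjusted p = 0.000643), while Gzmb fell by 3.30 ± 0.46 (adjusted p = 0.000122) and Tgm2, a transglutaminase, by 2.71 ± 0.32. Of 30 ATF4 targets 15 rose and 0 fell (20 and 0 adjusted over the list alone, median 0.50, camera adjusted p = 1.42e-13, adjusted p = 0.0117 with an estimated correlation), and Slc7a3 rose by 2.22 ± 0.16. Of 15 transporters 3 rose (5 adjusted over the list alone, camera Up, adjusted p = 0.028, adjusted p = 0.262 with an estimated correlation), with a mean of 0.25 and a median of -0.01. Cholesterol genes fell in 17 of 19 cases (19 adjusted over the list alone, median -1.43, camera adjusted p = 7.61e-32, adjusted p = 0.00266 with an estimated correlation). Glycolysis genes fell in 10 of 14 (12 adjusted over the list alone, median -0.67, camera adjusted p = 5.2e-10, adjusted p = 0.104 with an estimated correlation). Interferon response genes fell in 8 of 20 cases (12 adjusted over the list alone, median -0.49, camera adjusted p = 4.87e-06, adjusted p = 0.0378 with an estimated correlation). Stat2, which relays interferon signals, fell by 1.13 ± 0.17. Autophagy genes fell in 1 of 18 cases (2 adjusted over the list alone, camera adjusted p = 0.0167, adjusted p = 0.262 with an estimated correlation), which was Bnip3, a mitophagy receptor (-1.54 ± 0.25).

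B cell markers rose in the low lysine arrays, with 6 of 11 called (7 adjusted over the list alone, median 0.65, camera adjusted p = 7.62e-06, adjusted p = 0.11 with an estimated correlation) and the low-affinity IgE receptor Fcer2a at 1.30 ± 0.20 (adjusted p = 0.000382). Low lysine replicate 1 had the highest B cell level (6.84, against 6.10 and 5.86) and the lowest G2/M level (5.99, against 6.96 and 7.98), where full medium had G2/M levels of 8.77 to 8.89. Granulocyte and mast cell genes fell in 1 of 14 cases while the list as a whole passed in the other direction (1 rose and 1 fell adjusted over the list alone, median 0.27, camera Up, adjusted p = 0.028, adjusted p = 0.262 with an estimated correlation). Of 8 dendritic cell genes 1 fell (1 adjusted over the list alone, camera adjusted p = 0.645). The olfactory receptor gene Olfr68 (3.27 ± 0.47) had the largest rise, followed by Tnfrsf19 (2.27 ± 0.17) and with Olfr727 (1.97 ± 0.48), Cth (1.85 ± 0.28) and Olfr782 (1.83 ± 0.48). The call of Olfr727 ended without antigen replicate 2 or low lysine replicate 2 and that of Olfr782 without antigen replicate 3 or low lysine replicate 2 (highest adjusted p = 0.0872 and 0.12). In all 1936 genes were called, 553 higher (28.6%) and 1383 lower, with 18.4% higher after centring. Quantile normalization gave 558 higher and 676 lower. The count was 988, 926, 904, 903 and 3183 without antigen replicate 2, antigen replicate 3 and low lysine replicates 1, 2 and 3. With the compared groups alone, 968 genes were called. The SD of the mean G2/M level was 0.99 in low lysine and 0.07 in full medium. The SE of these genes comes from the spread shared by all groups and may be too small here.

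**Figure D2:**
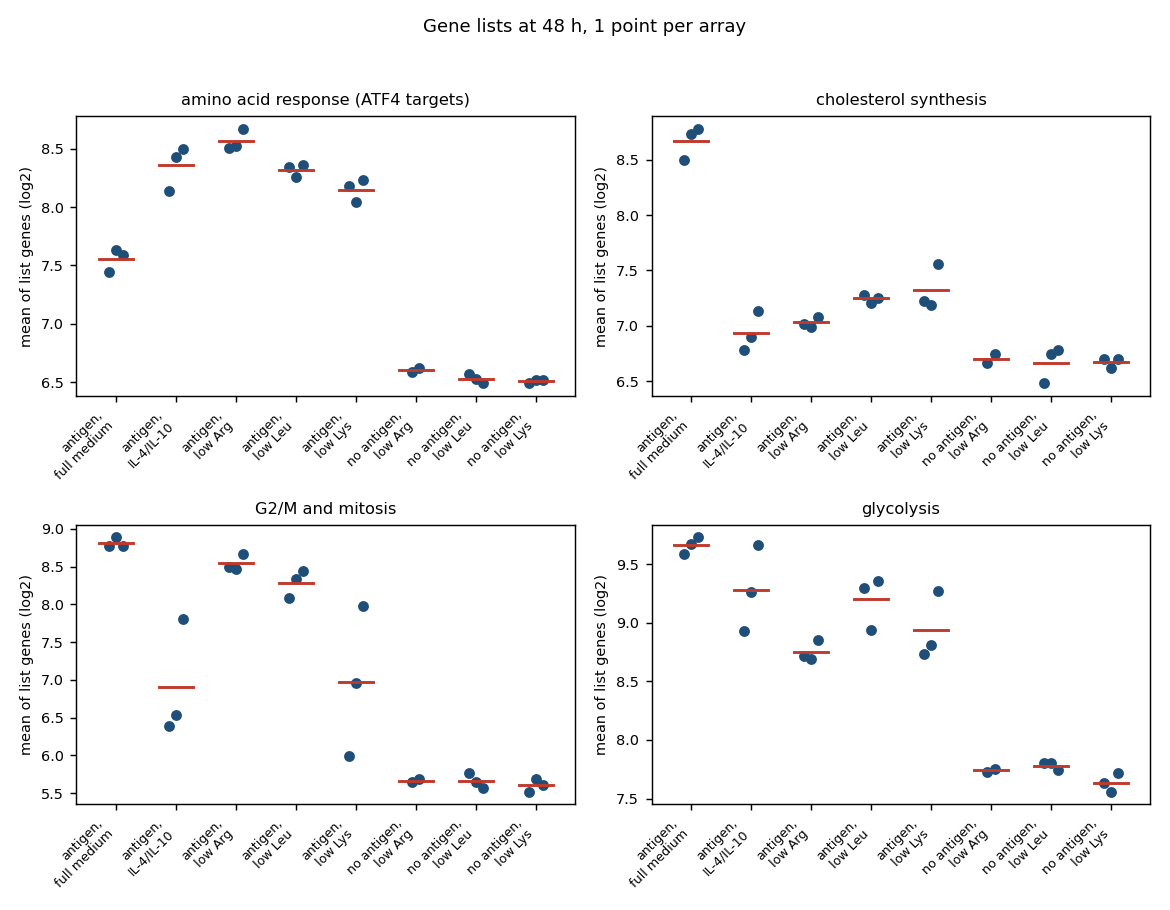
Mean level of the genes of a list (log2, vertical axis) in each group at 48 h (horizontal axis), with 1 point per array and a red line at the group mean. G2/M levels in low lysine were 5.99, 6.96 and 7.98, against 8.77 to 8.89 in full medium with antigen.

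The effects of the low media were compared with that of pretreated macrophages at 48 h. Across 22180 genes the pretreatment effect at 48 h correlated with low arginine at r = 0.61 (rho 0.61), with low leucine at 0.52 (rho 0.49) and with low lysine at 0.67 (rho 0.60), where the shared control arrays alone gave 0.50 (rho 0.47) in simulation. The covariance exceeded the simulated one by 0.0474, 0.0327 and 0.0718. Genes called lower in both numbered 408, 149 and 681 (41.7, 20.6 and 82.1 by chance) and higher in both 172, 106 and 143 (9.0, 6.9 and 15.0 by chance), with 5, 22 and 14 called in opposite directions. The full-medium arrays have other submitter ID runs than the low media, so low against full medium is confounded with the ID series, and the controls are shared, so that overlaps beyond chance are partly built in.

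Between the low media with antigen, low lysine stood apart in the G2/M genes, though its arrays varied. They averaged 5.99, 6.96 and 7.98 (SD 0.99), against 8.47 to 8.67 in low arginine (SD 0.11) and 8.09 to 8.44 in low leucine (SD 0.18). Low lysine replicate 3 thus lay close to low leucine, and the fit shares its estimate of the spread over all groups. With the compared groups alone, 139 genes were called for arginine against lysine and 50 for leucine against lysine. Low arginine exceeded low lysine in 24 of 31 G2/M genes (31 adjusted over the list alone, median 1.59, camera adjusted p = 8.2e-38, adjusted p = 0.07 with an estimated correlation). The kinetochore gene Ndc80, outside the list, was higher by 2.74 ± 0.40 (adjusted p = 0.000544). Low leucine exceeded low lysine in 15 of 31 G2/M genes (31 adjusted over the list alone, median 1.32, camera adjusted p = 8.09e-27, adjusted p = 0.148 with an estimated correlation). Il2 was lower in low arginine than in low lysine (-2.45 ± 0.29, adjusted p = 4.02e-05) and Gbp11 higher (2.52 ± 0.24, adjusted p = 5.26e-06), as was Nupr1 (1.97 ± 0.18, adjusted p = 3.36e-06). Il21 was higher in low leucine than in low lysine (3.12 ± 0.37, adjusted p = 0.000238), and Gpr183, a chemotactic receptor, was lower (-1.13 ± 0.15, adjusted p = 0.000238). Low arginine had less Rgs16 (-2.10 ± 0.17, adjusted p = 5.1e-07), Egln3 (-2.63 ± 0.33, adjusted p = 0.000352) and Fam171b (-1.68 ± 0.26) than low leucine, and more Slc7a11, the cystine transporter (1.21 ± 0.18), Jdp2 (1.06 ± 0.17), Itih5 (1.43 ± 0.22) and Mmp12 (1.40 ± 0.24). ATF4 targets were higher in low arginine than in low leucine in 4 of 30 cases (4 adjusted over the list alone, camera adjusted p = 6.47e-06, adjusted p = 0.138 with an estimated correlation). They were higher than in low lysine in 5 (8 adjusted over the list alone, camera adjusted p = 2.06e-10, adjusted p = 0.0673 with an estimated correlation). B cell markers were lower in low arginine than in low lysine in 1 of 11 cases (4 adjusted over the list alone, camera adjusted p = 6.42e-05, adjusted p = 0.189 with an estimated correlation). Called genes numbered 158 for arginine against leucine (52 higher, 106 lower), 715 for arginine against lysine (587 higher, 128 lower) and 416 for leucine against lysine (352 higher, 64 lower). Quantile normalization gave 90 of 173, 236 of 658 and 67 of 190 lower in the same order. The replicate number pairs the arrays of the first of these. As a block it gave 229 genes in the fit of all groups, and 1404 in a fit of the compared groups alone, which had 879 without a block. The ID run numbers these arrays the same way, and gave 110 as a block in a fit of the low media arrays only. Leaving out arginine replicates 1, 2 and 3 gave 48, 51 and 76 genes against leucine and 380, 403 and 329 against lysine. Leaving out leucine replicates 1, 2 and 3 gave 64, 67 and 78 against arginine and 180, 177 and 100 against lysine. Leaving out lysine replicates 1 and 2 gave 360 and 459 against arginine and 84 and 97 against leucine, with 1414 against leucine without lysine replicate 3.

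Antigen at 48 h raised T cell activation, ATF4 target and cell division genes in each low medium. Irf4 rose by 5.57 ± 0.14, 6.06 ± 0.13 and 5.60 ± 0.13 in low arginine (n = 3 and 2), leucine and lysine, Il2ra by 5.50 ± 0.15, 5.61 ± 0.13 and 5.53 ± 0.13, and Il2 by 2.85 ± 0.32, 4.73 ± 0.29 and 5.61 ± 0.29. S1pr1, the receptor for leaving lymph nodes, fell by 3.27 ± 0.24, 4.17 ± 0.22 and 3.47 ± 0.22 in the same order. T cell activation genes rose in 21, 22 and 22 of 24 cases and fell in 1 each (the same numbers adjusted over the list alone, camera adjusted p at most 8.35e-22, adjusted p = 0.000966, 0.00256 and 0.000979 with an estimated correlation). All 18 aminoacyl-tRNA synthetases rose in each (18 adjusted over the list alone, camera adjusted p at most 1.64e-20, adjusted p = 0.00472, 0.00718 and 0.00391 with an estimated correlation). ATF4 targets rose in 29, 29 and 27 of 30 cases (29 in each adjusted over the list alone, medians 1.90, 1.81 and 1.35, adjusted p = 0.000622, 0.00256 and 0.000979 with an estimated correlation). Ribosome biogenesis genes rose in 24, 26 and 25 of 26 cases (25, 26 and 26 adjusted over the list alone, adjusted p = 0.023, 0.0138 and 0.00666 with an estimated correlation). G2/M genes rose in 30, 30 and 24 of 31 (with 1 lower in low lysine, 30, 30 and 25 higher adjusted over the list alone, medians 2.96, 2.58 and 1.26, adjusted p = 0.0842, 0.111 and 0.294 with an estimated correlation). Regulatory T cell genes rose in 8, 7 and 6 of 10 cases (8, 8 and 7 adjusted over the list alone, camera adjusted p at most 0.000637, adjusted p = 0.028, 0.0532 and 0.0285 with an estimated correlation). Macrophage genes fell in 12, 16 and 14 of 24 cases (17, 17 and 16 adjusted over the list alone, camera adjusted p at most 2.1e-05, adjusted p = 0.174, 0.132 and 0.153 with an estimated correlation). Cd68, a lysosomal protein of macrophages, fell by 1.87 ± 0.31, 2.07 ± 0.28 and 1.65 ± 0.28. Interferon response genes in low leucine had a median of -0.21, which turned to 0.01 with quantile normalization, and a mean of 0.23 (camera adjusted p = 0.604). Mesothelial and stromal markers averaged 5.66 ± 0.02 (SD, n = 2), 5.76 ± 0.23 (SD, n = 3) and 5.40 ± 0.12 (SD, n = 3) without antigen and 5.14 ± 0.02, 5.16 ± 0.07 and 5.12 ± 0.14 (SD, n = 3) with it. Called genes numbered 6517 in low arginine (58.5% higher), 9165 in low leucine (52.7%) and 6884 in low lysine (59.4%), and after centring 83.0%, 75.9% and 79.0% were higher (differences of medians over the compared genes -0.19, -0.18 and -0.14). Quantile normalization gave 2576 higher and 2707 lower, 3433 and 3535, and 3049 and 3159, so the excess of higher genes depends on the scaling. Without low arginine replicate 1 of the arrays without antigen, where the lone array left is assumed to vary like the other groups, 3857 genes were called.

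The size of the antigen effect depended on the amino acid for 33 of 22180 genes by limma's moderated F test, with 1981 at an unadjusted p under 0.05. Il2 rose most in low lysine (adjusted p = 0.0156), Il21 rose by 2.30, 4.62 and 1.62 in low arginine, leucine and lysine (adjusted p = 0.0297), and Rgs16 by 1.91 ± 0.19, 4.28 ± 0.17 and 2.92 ± 0.17 (adjusted p = 0.000456). Cd80, a costimulatory ligand, rose by 2.44 ± 0.21 and 2.50 ± 0.19 in low arginine and leucine and measured 0.37 ± 0.19 in low lysine (adjusted p of the F test 0.000509). The count was 16, 13 and 18 without low arginine replicates 1, 2 and 3 with antigen, 10 without low leucine replicate 3 and 16, 20 and 218 without low lysine replicates 1, 2 and 3. It was 4 without the arrays of ID run 1, of which 3 were among the 33, and 164 with array weights. Without antigen, leaving out low arginine replicates 1 and 2 gave 8 and 12 and low lysine replicates 1, 2 and 3 gave 12, 14 and 21, and the lone low arginine array left is assumed to vary like the other groups. These genes were chosen after their values were seen.

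Without antigen the low media hardly differed. Limma called 0 genes between low arginine (n = 2) and low leucine, 1 between low arginine and low lysine and 2 between low leucine and low lysine, with 988, 1386 and 1609 at an unadjusted p under 0.05. Skap2, an adaptor protein of immune cells, was higher in low arginine (1.07 ± 0.17, adjusted p = 0.0451) and low leucine (1.01 ± 0.15, adjusted p = 0.0109) than in low lysine. Socs3, an inhibitor of cytokine signalling, was higher in low leucine than in low lysine (1.40 ± 0.20, adjusted p = 0.00978). Asns measured 0.24 ± 0.25 and 0.24 ± 0.22 against low lysine, and Mki67 0.51 ± 0.55 and 0.15 ± 0.49. Aminoacyl-tRNA synthetases, ribosome biogenesis and G1/S genes were higher as lists in low leucine than in low lysine (medians 0.13, 0.14 and 0.10, 0 genes called each, 2, 1 and 3 adjusted over the list alone, camera adjusted p = 0.0058, 0.0058 and 0.0471, adjusted p = 0.975 with an estimated correlation). The call of Skap2 against low lysine ended without low arginine replicate 1 or 2, without low leucine replicate 2 or 3, and without low lysine replicate 1 or 2, and that of Socs3 without low leucine replicate 3 or low lysine replicate 1 or 2 (highest adjusted p = 0.71, 0.203 and 0.178). Leaving out low arginine replicate 2 gave 8 genes against low leucine and 4 against low lysine, and leaving out low arginine replicate 1 gave 0 against low lysine. In these fits, and for Skap2 without either of them, the lone low arginine array left is assumed to vary like the other groups. Leaving out low leucine replicate 3 gave 1 against low arginine and 0 against low lysine. Against low lysine, 1 gene was left without low leucine replicate 2. Leaving out low lysine replicate 1 or 2 gave 0 genes against either medium, and replicate 3 gave 2 against low arginine and 14 against low leucine.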

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

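The tests that weigh explanations and the splits of the arrays were chosen only after the result was seen, except the one of RNA of other cells at 72 h, while the F test of the interaction was fixed beforehand.

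A difference between groups drew attention to 33 genes whose response to antigen differed between the low media at 48 h. The number rests on few arrays, with n = 2 for low arginine without antigen. Without the arrays of ID run 1 it was 4, of which 3 were among the 33. In low arginine, leucine and lysine, Il2 rose by 2.85 ± 0.32, 4.73 ± 0.29 and 5.61 ± 0.29 (adjusted p = 0.0156), Il21 by 2.30 ± 0.41, 4.62 ± 0.37 and 1.62 ± 0.37 (adjusted p = 0.0297), and Tnfsf11, the ligand RANKL, by 1.58 ± 0.19, 1.39 ± 0.17 and 2.72 ± 0.17 (adjusted p = 0.0297). Rgs16 rose by 1.91, 4.28 and 2.92 (adjusted p = 0.000456), Gbp11 by 3.36, 2.03 and 0.67 (adjusted p = 0.00486), Nupr1 by 3.02, 2.21 and 1.28 (adjusted p = 0.0156) and Ndc80 by 5.42, 4.08 and 1.98 (adjusted p = 0.0312). Cd80 changed by 2.44, 2.50 and 0.37 (adjusted p = 0.000509) and Il6st, a subunit of the IL-6 receptor, by 0.36, -0.70 and 0.24 (adjusted p = 0.0025). Between the times, the IL-4/IL-10 effect had opposite signs for Atp2a2, a calcium pump (-0.43 ± 0.12 at 48 h and 0.90 ± 0.24 at 72 h), and Pgap1 (0.56 ± 0.14 and -0.90 ± 0.25), and the difference was not tested. Signals also appeared in probe sets without a single gene, of which antigen changed 3378 of 16139 at 72 h and 3844 of 17824 in low leucine at 48 h.

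Of 1813 genes at least 2-fold lower with antigen at 72 h, the 1749 measured at 48 h had a median of -2.22 at 72 h, but of -0.16 less that of all genes at 48 h (-0.19 to -0.15 in the low media), while the 1715 genes that rose and were measured at 48 h had 1.53 and 1.02. A uniform shift of whole arrays left by the normalization as the whole cause is unlikely, since the median log2 fold change of all genes was 0.020. With centred arrays 71.2% of the 1813 stayed at least 2-fold lower (median -1.70). These genes were picked for their fall and centring adds a constant, so this share lends no separate support. RNA of mesothelial, stromal and macrophage cells in the arrays without antigen was consistent with the 48 h value, -0.16, measured in other cultures. The arrays at 72 h also differ from those at 48 h in platform, time and medium, so a later fall in the T cells themselves stays open, as untested.

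The G2/M genes were lower in low lysine than in full medium (median -1.88). A larger share of cells that had not been activated is unlikely as the whole cause, since 18 T cell activation genes raised by antigen in the other media had a median of -0.03 (quartiles -0.45 and 0.09). Their level in other cells was not checked, so the test cannot decide on a larger share of these, which stays open. Across low lysine replicates 1, 2 and 3 the B cell level (6.84, 6.10 and 5.86) ran opposite to the G2/M level (5.99, 6.96 and 7.98). The G2/M fall did not rest on 1 low lysine array, since leaving out each in turn gave medians from -1.35 to -2.30, with 23, 29 and 31 members called. Nor was a difference between the ID series enough, since low arginine exceeded low lysine by 1.59 with the ID run as a block (27 members called). A response of dividing cells to scarce lysine stays open, as untested.

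In all 3 low media, 161 genes were lower and 84 higher than in full medium. IL-4/IL-10 changed many of these the same way at 72 h on other arrays. They were 80 of 140 lower genes (8.4 for independent lists, 4 the other way) and 52 of 77 higher genes (2.9, 0 the other way). A difference between the submitter ID series unrelated to the genes of the pretreatment would not give this overlap. One that moved the same genes would, so the overlap cannot tell the ID series from the media. Nor can they be told apart for the 81 genes measured but not called at 72 h, since the design confounds them. A high Xist level did not separate the groups, as 1 array in each of the 4 groups with antigen had it. Nothing in the labels names donors, so other differences between animals stay open, as untested. The low amino acid media themselves stay open as the biological explanation, and whether pretreated macrophages deplete an amino acid was not measured.

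The arrays of each comparison of 3 and 3 arrays were also split in the 10 possible ways, and comparisons with the low arginine group without antigen were not split. In all of those split but 1, only 1 split, the real one, called as many genes as the real count. At 72 h the real counts were 6527, 1656 and 5557 for antigen, for IL-4/IL-10 and for both against no antigen (highest other 0 each). At 48 h they were 1916 for IL-4/IL-10 (highest other 12) and 1036, 603 and 1936 for low arginine, leucine and lysine (1, 0 and 1). Between the low media they were 158, 715 and 416 (0, 3 and 0), and for antigen in low leucine and lysine 9165 and 6884 (0 and 1). Low leucine against low lysine without antigen had 2 genes and 10 in another split, so that 2 splits called as many. Every other split mixes the compared groups, so their difference, whatever its cause, enters the spread and lowers the count. Low counts there cannot tell the treatment from the ID series. The 10 splits are too few for a share under 0.05. They ignore the replicate numbers, also where these were treated as pairing (IL-4/IL-10 at 72 h and low arginine against low leucine with antigen).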

How the results depend on the processing

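The tests with a replicate block over all groups, without ID run 1, and with an Xist block were chosen only after the result was seen, as were the list tests with an ID-run block, with each array left out or above the 40th percentile. Of 411 results for named genes 317 kept their side of the threshold under all settings (of 6781 values 6412 the same, 326 weaker, 43 stronger, 0 reversed), and of 400 for lists 194 did (of 4250 values 3854, 315, 81 and 0). Array weights gave 4061 genes for IL-4/IL-10 at 72 h, 2532, 1317 and 2930 for low arginine, leucine and lysine, 757, 1143 and 1099 for arginine against leucine, arginine against lysine and leucine against lysine with antigen, 2 for arginine against lysine without antigen and 164 for the interaction. Centring gave 12819 and 12195 for antigen and for IL-4/IL-10 with antigen at 72 h, where the arrays' medians over the compared genes differed, 95 for arginine against leucine, 0 for arginine against lysine without antigen and 21 for the interaction. A minimum of 2-fold gave, by its construction, 3629, 697 and 3062 at 72 h, 433 for IL-4/IL-10 at 48 h, 210, 173 and 441 for the low media, 30, 224 and 116 between them and 2023, 2616 and 1901 for antigen in them. The compared groups alone gave 1009 for IL-4/IL-10 at 72 h, 2472, 1654 and 968 for the low media, 879, 139 and 50 between them, and without antigen 0 for arginine against lysine and 0 for leucine against lysine. A replicate block in the fit of the compared groups gave 2685, 1768 and 1018 for the low media and 1404, 228 and 77 between the low media with antigen. Without antigen it gave 17 for arginine against lysine and 0 for leucine against lysine. Over all groups the block gave 638 for leucine against lysine with antigen and 3 for arginine against lysine without antigen. Quantile normalization gave 1234 for low lysine, 190 for leucine against lysine, 4 and 5 without antigen and 87 for the interaction. The ID-run block gave 3 and 7 without antigen. Without ID run 1 the counts were 49, 272 and 60 between the media, 11 and 17 without antigen and 4 for the interaction. Genes above the 40th percentile gave 61 for the interaction and r = 0.65 between the IL-4/IL-10 effects, and genes called in either r = 0.69. Leaving out 1 array gave 495 to 2225 and 1148 to 2111 for IL-4/IL-10 at 72 and 48 h, 577 to 710, 339 to 401 and 903 to 3183 for low arginine, leucine and lysine, 48 to 78, 329 to 1021 and 84 to 1414 between them, 3857 to 5543 for antigen in low arginine, 0 to 8, 0 to 4 and 0 to 14 without antigen and 8 to 218 for the interaction, and where this left 1 low arginine array without antigen, it is assumed to vary like the other groups. Apart from the 2-fold minimum, the cause was not tested. Counts held with no intensity trend, the median of probe sets and the Xist block, and an ID-run block between full and low media was not run because they share no run.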
